A study of Homo sapiens with 32 samples.

How the data were processed

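RNA from 3 pure cell populations and 8 mixtures of them was sequenced in 32 libraries, each read in 2 lanes of an Illumina HiSeq as pairs of 76 bases from TruSeq RNA v2 libraries, per the labels' protocols. The kit does not mark strand. The populations were a lung adenocarcinoma line, called H1092 here after the characteristics although the growth and extraction protocols give other line numbers, cancer-associated fibroblasts and tumour-infiltrating lymphocytes. Labelled percentages of each mixture were taken per the labels, which do not say what they count. The lane pair of each library was taken per the labels as well.

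The deposited files hold counts, whole numbers per Ensembl gene and lane, in 64 files of 40235 gene IDs each. The authors used TopHat, SAMtools and Picard with hg19, per the submitters' processing notes; versions, the order of steps, the counting tool and the annotation release are not given in the sources used here. File names say that reads were cleaned and duplicates removed. Only 10555 of the IDs are protein-coding and many well-known genes have no entry, so the files do not cover the whole transcriptome. Symbols came from GENCODE release 29, which matched 36219 IDs, and its newer genome build was used only for names, types and lengths, so no coordinates are given. IDs without a symbol are printed as they stand.

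The 2 lane files of each library were added up. Lanes of a library differed by about counting noise, with a chi-square per gene of 0.984 to 1.058 over genes of 20 counts or more, and 0 pairs of libraries were identical. Library totals were 6283596 to 10530498 counts, with medians of 8176814 in lanes 1 and 2 and 7764934 in lanes 3 and 4. A group at 0 counts allows up to 3 counts over its libraries, which is 0.105 CPM in H1092, 0.118 in CAF and 0.134 in TIL. Fold bounds use that floor, and ratios against 1 to 3 counts carry 95% counting intervals.

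CPM were computed here from the deposited counts on total gene counts, while log2 fold changes were scaled by TMM, so their ratios can differ. Of 20336 IDs with a count, filterByExpr kept 8602. Differences were tested with edgeR 4.0.16 (quasi-likelihood, 1 fit of 11 groups, common dispersion 0.000747, prior df 35.3) in R 4.3.3, with Benjamini-Hochberg adjustment at 0.05. The 10 contrasts were the 3 pairs of pure populations, 3 steps in TIL share, 3 exchanges of H1092 for CAF and the difference of the TIL step between backgrounds. All p-values are two-sided.

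Gene lists were tested with camera of limma 3.58.1 at a preset correlation of 0.01 and again with an estimated one, adjusted over lists within a contrast. Of 25 lists 24 could be tested; the mitochondrially encoded list matched 0 of 13 genes. Matched genes were few for some lists, such as 13 of 30 epithelial, 5 of 11 MHC class II, 6 of 15 MHC class I, 5 of 16 EMT and 20 of 49 ribosomal protein genes, and fewer still passed the filter. Lists overlap: TYROBP is on the myeloid and NK cell lists, and PRF1 on the cytotoxic effector and NK cell lists.

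Shares were estimated per library by non-negative least squares (Python 3.11.15, numpy 2.4.6, pandas 2.3.3, scipy 1.17.1) on 200 signature genes per population, each divided by its mean in its own population. Signature genes had an adjusted p under 0.05, a log2 fold of at least 3 over both others and 10 CPM or more; 261 genes qualified in H1092, 272 in CAF and 493 in TIL. They were chosen on the pure libraries only. Mixture means were compared with labels by exact sign-flip permutation and exact permutation of pairings. A departure was the mean over mixtures of the log2 of the observed level less the log2 of the share-weighted sum of pure levels, tested by the delta method on the edgeR fit, with a size threshold of 1.5-fold. No regrouping of libraries leaves the shares in place, so splits were not counted for departures.

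Named genes followed a rule. For pure populations they were drawn from the 10 largest changes per direction at 10 CPM or more with no overlap of libraries, where chance alone would part 10% of genes. For mixtures they came from the 5 largest per direction at 1 CPM or more, and for departures from the 10 largest per direction at 10 CPM or more. From each list up to 4 members with the largest change were eligible, and any member against its majority. Genes carried by some people only, genes of the sex chromosomes that tell sex, receptor segments and pseudogenes were left out. Groups, the tests of the comparisons, lists, the naming rule and all alternatives except the within-lane-pair fits were chosen before the data were examined; several tests of explanations were chosen later. Genes with near-identical copies (AKR1C1, HLA-C, ribosomal protein genes) and overlapping or antisense genes are uncertain, since shared reads could be counted elsewhere.

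The steps were tested on simulated data. For mixture B against E, 78% of genes changed 1.5-fold and 90% of those changed 2-fold were recovered, 100 of each among 8655, with 11 of 8429 unchanged genes called. For the difference between backgrounds, 65% and 81% were recovered, with 9 of 8429 unchanged genes called. For departures, of 100 genes changed 1.5-fold, 95 were called and 58 also passed the size threshold, and all 100 changed 2-fold passed, with 1 of 8160 unchanged genes called. Simulated shares were off by at most 0.237 points for H1092, 0.223 for CAF and 0.028 for TIL. Simulated libraries of a group shared a mean profile, and all genes a single fixed dispersion. No spread of composition between libraries and no lane difference entered the comparisons, so these figures cover neither. Simulated departures used the true shares, while the real ones used estimated shares, so the error of the estimate is not covered.

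Alternatives for the gene tests were DESeq2 size factors, total counts, no filter, the Wald test of DESeq2 1.42.0, only the groups compared, the lane pair as a term, either lane file alone, each library left out and a minimum of 2-fold. For shares they were 50 or 500 genes, undivided CPM, all tested genes, no genes of the top 10%, TMM-scaled CPM, either lane file, each library left out and each lane pair alone. Departures were repeated with labelled shares, TMM-scaled CPM, each lane pair, no size threshold, a minimum of 2-fold, every gene and each pure library left out. List tests were repeated with an estimated correlation, size factors and total counts. Fits within a lane pair for mixtures B against C and C against F were added after the data were seen.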

Results

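RNA was sequenced from 3 cultured cell populations and from 8 mixtures of them, which together made 32 libraries in 11 groups. The populations were a human lung adenocarcinoma line, called H1092 here, cancer-associated fibroblasts (CAF) and tumour-infiltrating lymphocytes (TIL). The protocols give other numbers for the carcinoma line than the characteristics do, so which line was used is not settled here. Each pure population and each mixture had 3 libraries, except mixture H with 2. The labelled composition, in percent H1092, CAF and TIL, was 45.6, 50.8 and 3.6 in mixture A, 61.9, 35.6 and 2.5 in B, 29.6, 68.0 and 2.4 in C, and 43.2, 49.7 and 7.1 in D. It was 63.0, 36.2 and 0.9 in mixture E, 30.0, 69.1 and 0.8 in F, 81.9, 17.7 and 0.4 in G, and 93.6, 6.0 and 0.4 in H. The labels do not say whether these percentages count cells or RNA. Total gene counts per library ran from 6283596 to 10530498, with a median of 8082472. The pure libraries, those of mixtures A and B and 1 library of mixture C were sequenced in lanes 1 and 2, and the other 16 in lanes 3 and 4. The 10 most abundant genes took 11.67 to 12.01% of the counts in CAF, 6.66 to 6.98% in H1092 and 6.39 to 6.56% in TIL.

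To describe the parts before the mixtures, the pure populations were compared pairwise over the 8602 genes tested. Each population had a set of genes at least 8-fold above both others: 507 in H1092, 447 in CAF and 722 in TIL. All 9 pure libraries came from lanes 1 and 2, so these comparisons lie within a single lane pair. Nothing in the labels says that the libraries of a population came from separate cultures. The p-values of gene tests and departures below therefore measure only the spread between libraries, taken over all groups, which may be technical. Those of camera compare a list with the other genes, and the permutation p-values rest on the mixture means. None of them is known to cover a spread between cultures. Fold bounds and count intervals cover counting error only.

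Epithelial and NRF2 target genes were mostly higher in H1092 than in CAF, and matrix and fibroblast genes were lower. CLDN1, a tight junction protein, reached 261 ± 8.76 CPM (SD, n = 3) in H1092 against 0.789 ± 0.189 in CAF. The neutral amino acid transporter gene SLC6A15 was at 198 ± 4.25 CPM and at 0 counts in all CAF libraries. COL6A3, a chain of collagen VI, was at 8630 ± 414 CPM in CAF and 7.56 ± 0.212 in H1092. Between H1092 and CAF, 3553 genes were higher and 3358 lower by edgeR, of which 1878 and 1647 differed at least 2-fold.

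Of the 10 epithelial genes tested, 9 were higher in H1092 and 1 was lower, with a median log2 fold change of 5.74, or 5.21 with genes at 0 counts set to their bound (camera adjusted p = 0.0152, and adjusted p = 0.0453 with an estimated correlation). CLDN1 differed by 7.95 ± 0.10 on the log2 scale (SE, edgeR adjusted p = 1.34e-56). The exception was DSP, which encodes the desmosomal protein desmoplakin. It was at 26.9 ± 2.21 CPM in CAF and 2 counts in all of H1092, a ratio of 384 with a 95% counting interval from 106 to 3180. EVPL, which encodes envoplakin of the cornified envelope, was at least 317-fold higher in H1092, and MEGF10, an engulfment receptor gene, at least 464-fold. Among long noncoding RNAs, LINC00824 reached 451 ± 13.4 CPM and was at least 3820-fold higher.

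All 20 matrix genes tested were lower in H1092 than in CAF, with a median of −3.97 (camera adjusted p = 4.05e-09, and 0.0155 as the adjusted p with an estimated correlation). COL6A3 differed by −10.55 ± 0.07 on the log2 scale (edgeR adjusted p = 1.82e-70), the elastic fibre gene FBLN5 by −9.40 and COL5A2 by −8.65. The basement membrane collagen gene COL4A1 was at 0.129 ± 0.111 CPM in H1092 and 1710 ± 25.8 in CAF. All 16 fibroblast genes were lower as well (camera adjusted p = 1.92e-06, and adjusted p = 0.0155 with an estimated correlation), among them PDGFRB, the platelet-derived growth factor receptor beta, by −5.91, and calponin, CNN1, by −5.73. CD248, which encodes endosialin of stromal cells, had 1 count in H1092 against 1300 ± 13.0 CPM in CAF, a ratio of 37000 with a counting interval from 6640 to 1460000. ACAN, which encodes the cartilage proteoglycan aggrecan, was at least 2380-fold lower in H1092, ACTG2, a smooth muscle actin gene, at least 1180-fold, and the prion protein gene PRNP at least 4060-fold.

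NRF2 target genes were higher in H1092 in 10 of 12 cases and lower in 2 (camera adjusted p = 0.0147, and adjusted p = 0.0497 with an estimated correlation). The aldo-keto reductase AKR1C1 was at 1300 ± 9.29 CPM against 61.2 ± 1.19, and AKR1B10 was higher by 7.61. HMOX1, which encodes haem oxygenase, was against this majority, at 77.3 ± 2.29 CPM against 293 ± 4.06. Cholesterol synthesis genes were higher in 7 of 8 cases (camera adjusted p = 0.0249), a call lost with an estimated correlation (adjusted p = 0.06). DHCR7, of the last step to cholesterol, was higher by 1.99. Immediate early and heat shock genes were lower in 13 of 17 cases and higher in 4 (camera adjusted p = 0.0169, but adjusted p = 0.118 with an estimated correlation). FOS stood at 924 ± 22.3 CPM in CAF and 42.7 ± 2.75 in H1092, while MYC stood at 2100 ± 46.8 CPM in H1092 against 124 ± 6.83.

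The glycolysis and hypoxia list was lower in 12 of 14 cases and higher in 2 (camera adjusted p = 0.00552, but adjusted p = 0.153 with an estimated correlation). Its members include ADM, which encodes the vasodilator peptide adrenomedullin and differed by −3.61, and CA12, a carbonic anhydrase gene, which was higher by 1.42. Ribosomal protein genes were higher in 14 cases, lower in 4 and not past the test in 2 (camera adjusted p = 0.0169, but adjusted p = 0.634 with an estimated correlation). All 3 neuroendocrine genes were higher, with SCG2, a secretory granule protein gene, at 172 ± 8.05 CPM against 6.64 (camera adjusted p = 0.0375, but adjusted p = 0.0867 with an estimated correlation). Lists not called by camera were lung lineage (3 higher, 1 lower, adjusted p = 0.306), T cell (6 higher, 1 lower, 19 not past the test, 0.358), cytotoxic effector (5 higher, 15 not, 0.306), and T cell activation and checkpoint (7 higher, 2 lower, 8 not, 0.264). Also not called were B and plasma cell (2 higher, 2 lower, 2 not, 0.79), NK cell (2 higher, 6 not, 0.597), endothelial (1 higher, 3 lower, 1 not, 0.474), MHC class I (3 higher, 3 lower, 0.945) and interferon response (11 higher, 7 lower, 5 not, 0.529). Cell cycle (6 higher, 14 lower, 0.0987, with a median of −0.37 that became 0.02 under total counts), EMT regulators (1 higher, 4 lower, 0.075), histones (7 higher, 1 lower, 2 not, 0.0809) and the broadly expressed reference genes (11 higher, 6 lower, 1 not, 0.3) were not called either. None of the 5 myeloid genes (0.932) and none of the 5 MHC class II genes (0.945) passed edgeR's test, and 0 of them passed at an unadjusted p under 0.05 or by DESeq2.

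Counts adjusted over the list alone were the same as those over all genes tested for every list in H1092 against CAF. Scaling by total counts moved the median log2 fold change of all genes from 0.001 to 0.398 and the calls to 4761 higher and 2336 lower. Under it the epithelial and neuroendocrine lists were no longer called (adjusted p = 0.0604 and 0.0952), the EMT list was called toward CAF and the reference list toward H1092 (0.0242 and 0.0487), and the median of the MHC class I list went from −0.20 to 0.20.

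**Figure D1:**
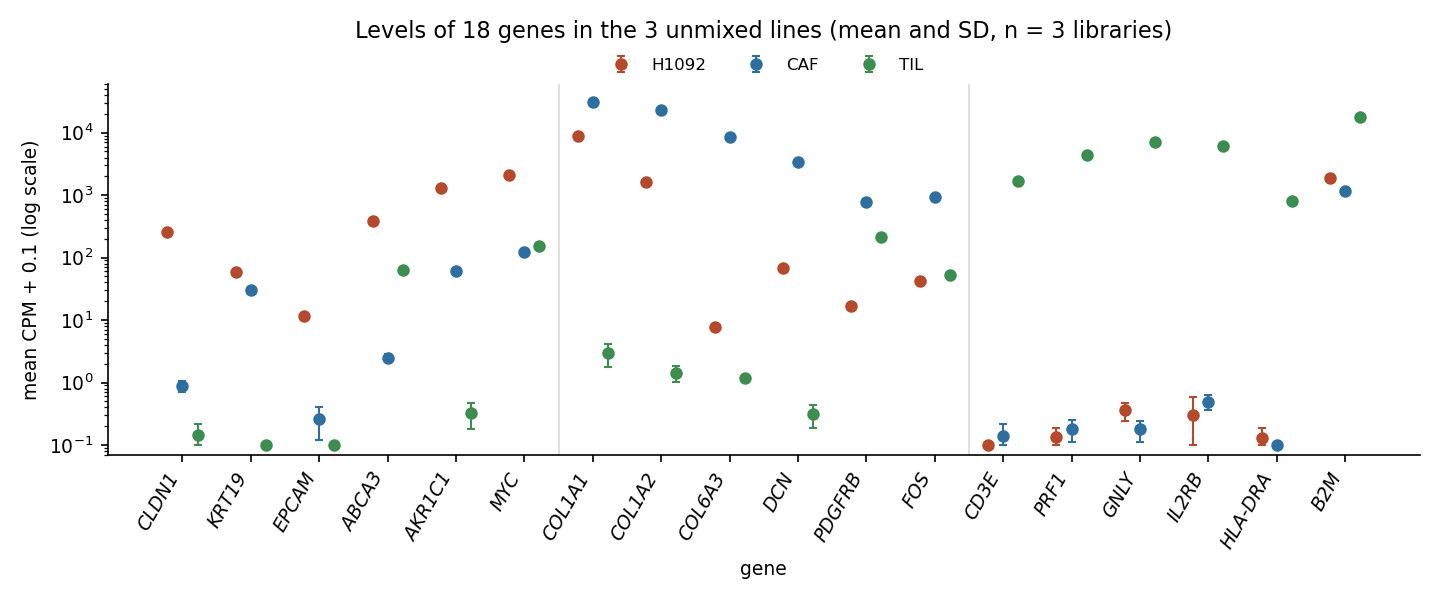
Mean CPM plus 0.1 of 18 named genes in the 3 pure H1092, 3 pure CAF and 3 pure TIL libraries, on a log scale, with SD bars whose lower ends are not drawn under 0.1. COL1A1 spans 30800 CPM in CAF, 8790 in H1092 and 2.84 in TIL, while GNLY is at 7150 CPM in TIL.

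T cell, cytotoxic effector and antigen presentation genes were higher in TIL than in H1092, and epithelial, matrix and fibroblast genes were mostly higher in H1092. CD3E, a chain of the T cell receptor complex, was at 1670 ± 36.3 CPM in TIL and at 0 counts in H1092, at least 15800-fold apart. The pore-forming protein gene PRF1 reached 4410 ± 36.8 CPM in TIL against 1 count in H1092, a ratio of 126000 with a counting interval from 22500 to 4960000. In H1092, the Wnt antagonist DKK1 was at least 1910-fold above TIL, and the transcription factor gene SOX9, at 164 ± 4.43 CPM, at least 1220-fold. edgeR called 4132 genes higher in H1092 and 3525 higher in TIL, of which 2868 and 2070 differed at least 2-fold.

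All 26 T cell genes were higher in TIL, with a median of −13.71, or −11.79 with genes at 0 counts at their bound (camera adjusted p = 1.49e-11, and adjusted p = 0.0145 with an estimated correlation). The kinase ZAP70 of receptor signalling was at least 5540-fold and CD3D at least 4960-fold higher. All 20 cytotoxic effector genes were higher in TIL (camera adjusted p = 3.35e-09, and adjusted p = 0.0056 with an estimated correlation). GNLY, the antimicrobial granulysin, stood at 7150 ± 178 CPM and the granzyme GZMA at 4410 ± 113 CPM. Of the activation and checkpoint genes, 14 were higher in TIL and 3 in H1092 (camera adjusted p = 0.000416, and adjusted p = 0.0155 with an estimated correlation). IL2RB, a chain of the interleukin 2 receptor, was at 6130 ± 53.6 CPM in TIL and differed by −15.08, and the receptor PDCD1 was at least 553-fold higher. TNFRSF9, a costimulatory receptor, was on the other side, at 71.2 ± 0.594 CPM in H1092 and 34.7 ± 1.21 in TIL.

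Antigen presentation separated the 2 populations as well. All 5 MHC class II genes were higher in TIL (camera adjusted p = 0.00155, and adjusted p = 0.0249 with an estimated correlation), with HLA-DRA at 805 ± 14.6 CPM against 1 count. All 6 MHC class I genes were higher in TIL, with a median of −3.39 (camera adjusted p = 0.000261, and adjusted p = 0.0056 with an estimated correlation). B2M, the light chain of class I molecules, was at 17600 ± 422 CPM in TIL and 1870 ± 29.2 in H1092. Of the myeloid list, 4 genes were higher in TIL and 1 in H1092 (camera adjusted p = 0.0287, and adjusted p = 0.0418 with an estimated correlation), and all 8 NK cell genes were higher in TIL (camera adjusted p = 0.000261, and adjusted p = 0.0145 with an estimated correlation). TYROBP, an adaptor of activating receptors on both lists, was at least 2710-fold higher, and the NK cell receptor gene NCR1 at least 938-fold.

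Toward H1092, 9 of 10 epithelial genes were higher (camera adjusted p = 0.00786, and adjusted p = 0.0187 with an estimated correlation), with the simple keratin KRT19 at least 442-fold and the adhesion molecule EPCAM at least 87.3-fold up. Matrix genes were higher in H1092 in 18 of 20 cases (camera adjusted p = 1.58e-05, and adjusted p = 0.0281 with an estimated correlation) and fibroblast genes in 13 of 16, with 2 lower (camera adjusted p = 0.000994, and adjusted p = 0.0338 with an estimated correlation). COL1A1, the major chain of collagen I, was at 8790 ± 429 CPM in H1092 against 2.84 ± 1.19 in TIL, and the matricellular gene POSTN at 2030 ± 33.6 against 0.36 ± 0.263. Higher in TIL within these lists were PDGFRB, at 211 ± 9.81 CPM against 16.7 ± 1.75, COL5A2, at 40.3 ± 1.65 against 7.77 ± 0.24, and FBLN5, at 11.6 ± 1.07 against 1.09 ± 0.331. NRF2 targets were higher in H1092 in 11 of 12 cases (camera adjusted p = 0.000591, and adjusted p = 0.013 with an estimated correlation), with AKR1C1 up by 12.28, and so were all 5 EMT regulators (camera adjusted p = 0.00321, and adjusted p = 0.0145 with an estimated correlation). Cell cycle genes were higher in TIL in 13 of 20 cases and lower in 7 (camera adjusted p = 0.042), a call lost with an estimated correlation (adjusted p = 0.0728). The proliferation marker MKI67 was at 1380 ± 19.4 CPM in TIL and 458 ± 19.5 in H1092. HOPX, a homeodomain gene of the lung lineage list, reached 733 ± 30.2 CPM in TIL against 2 counts in H1092. No count in H1092 against TIL changed when adjusted over the list alone. The endothelial list had a median of −1.94 while camera pointed up, and the reference list a median of 0.14 while camera pointed down (adjusted p = 0.913 for both). Scaling by total counts moved the median of all genes from 0.155 to 0.278, and it called the interferon response list toward TIL and the ribosomal protein list toward H1092 (adjusted p = 0.0423 and 0.0268, against 0.0608 for both with TMM).

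Matrix and fibroblast genes were mostly higher in CAF than in TIL, and T cell and cytotoxic effector genes were higher in TIL. COL1A2 was at 22700 ± 240 CPM in CAF and 1.35 ± 0.419 in TIL, and COL1A1 at 30800 ± 667 against 2.84. F3, the tissue factor that starts coagulation, was at 849 ± 22.3 CPM in CAF and at 0 counts in TIL, at least 6330-fold apart. In TIL, the interleukin 10 receptor gene IL10RA was at 1610 ± 0.85 CPM and the adhesion receptor CD2 at 1470 ± 9.21 CPM, at least 13600-fold and 12400-fold above CAF. Higher in CAF were 3816 genes and higher in TIL 3522, of which 2541 and 1964 differed at least 2-fold by edgeR.

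All 20 matrix genes were higher in CAF, with a median of 12.57, or 12.16 with genes at 0 counts at their bound (camera adjusted p = 9.15e-11, and adjusted p = 0.00412 with an estimated correlation). The small proteoglycan DCN was higher by 14.05 ± 0.09 (edgeR adjusted p = 7.99e-73). The fibroblast list was higher in CAF in 15 of 16 cases, with POSTN up by 12.85 and the actin-binding caldesmon CALD1 by 12.37 (camera adjusted p = 2.84e-06, and adjusted p = 0.00672 with an estimated correlation). The calcium-binding protein gene S100A4 was the exception, at 1610 ± 74.9 CPM in TIL and 197 ± 2.36 in CAF. All 5 EMT regulators were higher in CAF (camera adjusted p = 0.00143, and adjusted p = 0.00678 with an estimated correlation), including TGFBI at 5900 ± 41.3 CPM against 8.14. The NRF2 list was higher in CAF in 8 cases and lower in 2 of 12 (camera adjusted p = 0.037, but adjusted p = 0.0707 with an estimated correlation).

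Toward TIL, all 26 T cell, 20 cytotoxic effector, 8 NK cell, 5 MHC class II and 6 MHC class I genes were higher. Their camera adjusted p-values were 2.48e-12, 6.85e-10, 0.000106, 0.00143 and 0.000254, and with an estimated correlation 0.00678, 0.00412, 0.00741, 0.0212 and 0.00412. CD8A, a co-receptor chain of cytotoxic T cells, was at 3050 ± 29.1 CPM in TIL against 1 count in CAF, and CD247 was at least 6040-fold higher. Activation and checkpoint genes were higher in TIL in 16 of 17 cases (camera adjusted p = 2.84e-06, and adjusted p = 0.00412 with an estimated correlation), with CD38 at least 2540-fold up. The myeloid list was higher in TIL in 4 cases and lower in 1 (camera adjusted p = 0.0271, and adjusted p = 0.0425 with an estimated correlation). Interferon response genes were higher in TIL in 15 cases, lower in 7 and not past the test in 1 (camera adjusted p = 0.0113, and adjusted p = 0.0313 with an estimated correlation). BST2, which tethers virus particles, was at 382 ± 22.3 CPM against 1.35 ± 0.52, whereas IFIT1, an RNA-binding antiviral protein gene, was higher in CAF by 5.75. Cholesterol synthesis genes were higher in TIL in 7 of 8 cases (camera adjusted p = 0.0054, and adjusted p = 0.0126 with an estimated correlation), with INSIG1 at 201 CPM against 53.2. All 4 lung lineage genes were higher in TIL (camera adjusted p = 0.0175, but adjusted p = 0.0885 with an estimated correlation). Adjusted over the list alone, the counts changed for 1 list only, the histones, from 4 to 2 genes higher in TIL with 1 lower. Scaling by total counts moved the median of all genes from 0.057 to −0.177, and it called 3 more lists toward TIL, cell cycle, ribosomal protein and reference genes, at adjusted p-values of 0.0297, 0.0496 and 0.0496 against 0.0632, 0.56 and 0.406 with TMM.

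The labels give the composition of each mixture, so the next question was how far the counts followed it. Shares were estimated from 200 signature genes per population by non-negative least squares. The estimated H1092 share rose from 29.53 ± 1.77% (SD, n = 3) in mixture C to 92.56 ± 0.17% (n = 2) in mixture H, and the CAF share from 6.73 ± 0.04% in H to 69.66 ± 1.53% in F. TIL ran from 0.61 ± 0.11% in mixture G to 5.59 ± 0.25% in D. Over the 8 mixture means, Pearson's r between estimated and labelled percent was 0.9998 for H1092 and for CAF and 0.9972 for TIL (exact permutation p = 2.5e-05, 2.5e-05 and 9.9e-05, adjusted over the 3 relations to 3.7e-05, 3.7e-05 and 9.9e-05). The value 2.5e-05 is the smallest p that the pairings can give. Spearman's rho was 1.0, 1.0 and 0.9286 (exact permutation p = 5e-05, 5e-05 and 0.0022). Without the 2 mixtures farthest from the median label, r was 0.9994, 0.9997 and 0.987 (exact permutation p = 0.0014, 0.0014 and 0.0056). Within lanes 3 and 4, which hold libraries of 6 mixtures, r was 0.9998, 0.9999 and 0.998 (exact permutation, adjusted p = 0.0021, 0.0021 and 0.0056), and lanes 1 and 2 hold 3 mixtures, too few for a correlation.

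**Figure D2:**
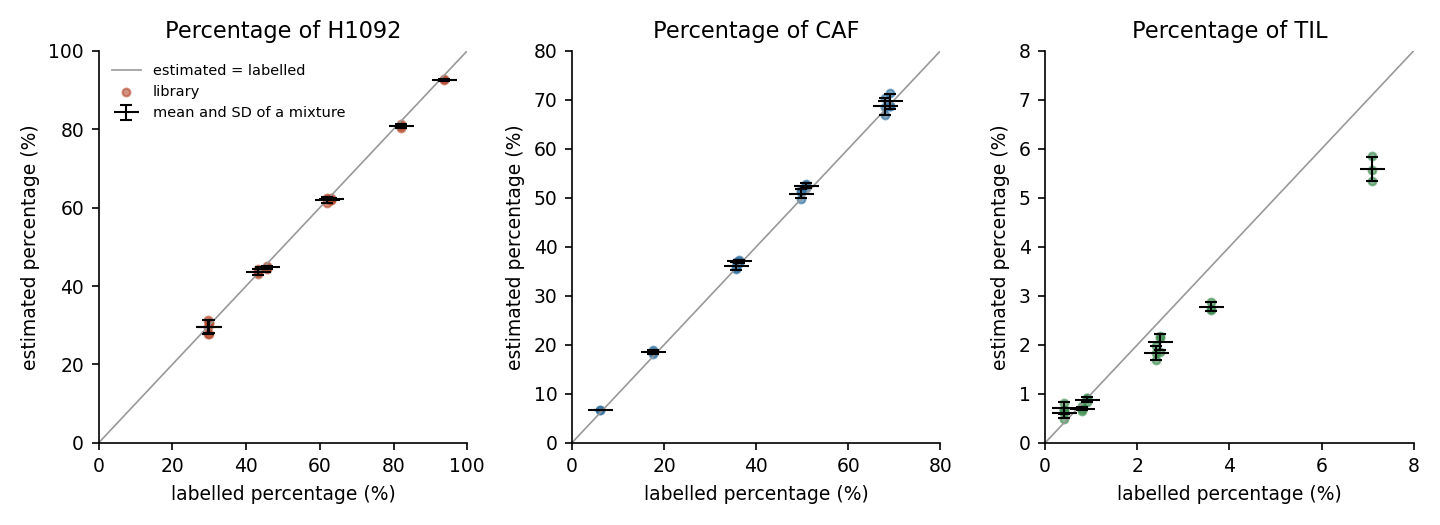
Estimated against labelled percent of H1092, CAF and TIL in the 8 mixtures, each panel in percent, with points for the 23 libraries, mean ± SD per mixture (n = 3, mixture H n = 2) and a diagonal line where both are equal. TIL lies under the line in mixture D, at 5.59% for a label of 7.1%, and above it in mixture H, at 0.71% for a label of 0.4%.

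The H1092 and CAF estimates followed the labels with small offsets, and the TIL estimates with offsets larger relative to their spread between libraries. The CAF share lay above its label in 8 of 8 mixtures, by 0.85 points on average (exact sign-flip permutation p = 0.0078, the smallest the sign flips can give, adjusted p = 0.023). All 8 estimates use the same pure libraries as reference, so an error in a reference profile would move them together. The sign flips treat the mixtures as independent and do not cover such an error. The H1092 share was above its label in 2 mixtures and below it in 6, by −0.48 points on average (exact permutation p = 0.078, adjusted p = 0.12). These offsets compare with a pooled SD between libraries of 0.98 points for CAF and 0.969 for H1092. For TIL the mean difference was −0.37 points (exact permutation p = 0.12, adjusted p = 0.12), with a slope of 0.741 on the labelled percent against 0.985 for H1092 and 1.001 for CAF. That mean averages opposite differences, below the label in 6 mixtures and above it in 2. They ran from −1.51 points in mixture D to 0.31 in H, against a pooled SD between libraries of 0.14 points. The estimated TIL share was 0.771, 0.823, 0.763 and 0.787 times the label in mixtures A to D, 0.982 in E, 0.872 in F, 1.517 in G and 1.778 in H. The labels of G and H carry a single digit for TIL, so rounding limits those ratios. The log2 ratio of CAF to H1092 content, estimated over labelled, averaged 0.0596 (exact permutation p = 0.0078, adjusted p = 0.016), and that of TIL to H1092 averaged −0.016 (exact permutation p = 0.93, adjusted p = 0.93). The TIL ratio ran from −0.387 in mixture C to 0.834 in H, so its mean near 0 hides opposite values. The signs of the CAF and H1092 offsets and of the CAF ratio depended on the scaling. With TMM-scaled CPM the offset was −4.52 points for CAF and 4.81 for H1092, and the log2 content ratio of CAF was −0.3375. That shift follows from the factors dividing the pure profiles, 0.842 to 0.86 in CAF and 1.103 to 1.141 in H1092. With genes left undivided by their own-population mean, the offsets were −0.03 points for CAF and 0.34 for H1092, and the CAF ratio was −0.0122. Without library 1 of H1092 the H1092 offset was −0.72 and passed the threshold, while the CAF ratio missed it without library 2 of C (0.052), without library 1 of F (0.0517), with 50 genes (0.0381) and with all tested genes (0.0346). Within lanes 1 and 2 (3 mixtures) the mean offsets were 0.30 points for H1092, 0.35 for CAF and −0.66 for TIL, and within lanes 3 and 4 (6 mixtures) −0.65, 0.92 and −0.27 (exact permutation, adjusted p = 0.14, 0.094 and 0.47). The log2 content ratio of CAF was −0.0048 in lanes 1 and 2 and 0.0746 in lanes 3 and 4 (exact permutation, adjusted p = 0.062), and that of TIL −0.4052 and 0.1003 (exact permutation, adjusted p = 0.66). With 6 mixtures the sign flips reached the smallest p they can give for both CAF values, so the lost calls in lanes 3 and 4 say little about either value.

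A pair of mixtures with similar ratios of H1092 to CAF shows what a larger TIL share did. In mixture D against mixture A (7.1 against 3.6% TIL), lymphocyte genes rose together by about their share. LCK, the kinase that starts T cell receptor signalling, was at 80.4 ± 2.5 CPM in D and 37.0 ± 3.27 in A, a log2 change of 1.12 ± 0.07 (edgeR adjusted p = 4.57e-21). IL2RB rose from 177 ± 7.54 to 344 ± 17.1 CPM. B2M, which all cells use, rose from 1940 ± 13.4 to 2550 ± 46.2 CPM. Over all genes, 1166 rose and 952 fell, of which 162 and 7 changed at least 2-fold. D lay in lanes 3 and 4 and A in lanes 1 and 2, so neither lane pair holds both, and only a fit with the lane pair as a term could part them. That fit, whose lane term rests on 1 library of mixture C against 2, called 162 genes higher and 22 lower. The 1 library was estimated at 31.3% H1092 and the 2 at 27.8 and 29.4%, so the lane term may also carry a difference in composition. With it, the median log2 change of the H1092 signature genes went from −0.06 to 0.08.

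All 26 T cell genes rose in D, with a median of 0.99 (camera adjusted p = 1.15e-19, and adjusted p = 0.00179 with an estimated correlation). SIT1, a signalling adaptor, rose by 1.44, and by 1.02 with the lane pair as a term, which did not pass (edgeR adjusted p = 0.076). Cytotoxic effector genes rose in 18 of 20 cases (camera adjusted p = 5.73e-15, and adjusted p = 0.000574 with an estimated correlation), with the granzyme GZMH up by 1.37, or by 0.83 and not past the test with the lane pair as a term. The activation list rose in 9 of 17 cases (camera adjusted p = 3.73e-05, and adjusted p = 0.0067 with an estimated correlation), with the inhibitory receptor LAG3 up by 1.01. Rises also came in 3 of 5 myeloid, 7 of 8 NK cell, 5 of 5 MHC class II and 4 of 6 MHC class I genes (camera adjusted p = 0.00269, 4.73e-06, 1.37e-05 and 4.03e-06, and adjusted p = 0.0103, 0.00385, 0.00432 and 0.000574 with an estimated correlation). HLA-DRA rose by 1.08 and HLA-C by 0.47. Ribosomal protein genes rose in 20 of 20 cases by a median of 0.26 (camera adjusted p = 1.5e-23, and adjusted p = 0.0205 with an estimated correlation). RPS16 among them rose by 0.37, and by 0.23 with the lane pair as a term, which no longer passed the test. That is 1 member of the list, which was not tested as a whole with that term. Over its 20 genes the lane term had a median of 0.10, smaller than the median rise of 0.26. Matrix genes fell in 11 of 20 cases, with a list median of −0.10 (camera adjusted p = 0.00635, but adjusted p = 0.182 with an estimated correlation), with COL12A1 at −0.30 and at −0.10 with the lane pair as a term. Glycolysis and hypoxia genes rose in 4 of 14 cases (camera adjusted p = 0.00474, but adjusted p = 0.182 with an estimated correlation), and reference genes rose in 9 of 18 with 1 lower (camera adjusted p = 9.15e-05, but adjusted p = 0.113 with an estimated correlation). Adjusted over the list alone, the counts were 10 for activation, 4 for myeloid, 8 for NK cell and 10 for reference genes, and the same as over all genes for the other lists named here. The largest increases of all were those of small noncoding RNAs, with 7SK, a regulator of transcription elongation, up by 3.11 and ENSG00000265150 by 3.57; with the lane pair as a term these were 0.45 and 0.77, not past the test.

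In an H1092-rich background, T cell, cytotoxic effector and MHC class II genes rose in mixture B against mixture E (2.5 against 0.9% TIL). PTPRC, the pan-leukocyte phosphatase CD45, rose from 26.2 ± 4.32 to 75.5 ± 8.84 CPM, a log2 change of 1.52 ± 0.09 (edgeR adjusted p = 1.99e-20). IL2RB went from 56.4 ± 5.88 to 141 ± 9.79 CPM, and CD74, the invariant chain of MHC class II, from 38.8 ± 5.25 to 82.1 ± 7.66. edgeR called 1052 genes higher and 687 lower, of which 180 and 10 changed at least 2-fold. B lay in lanes 1 and 2 and E in lanes 3 and 4, so no value within a lane pair can be had; with the lane pair as a term, 153 genes were higher and 84 lower.

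T cell genes rose in 23 of 26 cases by a median of 1.19 and cytotoxic effector genes in 16 of 20 by 1.17 (camera adjusted p = 3.92e-23 and 1.02e-16, and adjusted p = 0.000988 and 0.000284 with an estimated correlation). RGS1, a regulator of G protein signalling, rose by 2.44 and the costimulatory receptor ICOS by 2.06, from 0.653 to 2.76 CPM. With the lane pair as a term ICOS rose by 1.71 and did not pass. Their levels in E rest on 8 and 16 counts, and the labelled shares predict 1.48 for a gene found in TIL alone. TIGIT, an inhibitory receptor, rose by 1.40 and the killer cell lectin-like receptor KLRB1 by 1.56. Activation genes rose in 8 of 17 cases, myeloid in 3 of 5, NK cell in 7 of 8 and MHC class II in 4 of 5 (camera adjusted p = 4.35e-05, 0.00519, 6.08e-07 and 0.000116, and adjusted p = 0.00931, 0.0158, 0.00221 and 0.0107 with an estimated correlation). Of the MHC class I genes, called as a list in D against A, 1 of 6 rose (camera adjusted p = 0.461), or 3 adjusted over the list alone, and the difference between the contrasts was not tested. Here ribosomal protein genes fell, 19 of 20 with a median of −0.19 (camera adjusted p = 1.59e-20, and adjusted p = 0.0389 with an estimated correlation), whereas they rose in D against A. RPS19 changed by −0.29 and RPL28 by −0.28. With the lane pair as a term both missed the threshold, at −0.18 and −0.17, and the list as a whole was not tested with that term. Over its 20 genes the lane term had a median of 0.10, smaller in size than the median of −0.19. Glycolysis and hypoxia genes fell in 5 of 14 cases, immediate early and heat shock genes in 4 of 17 with 1 higher, and reference genes in 8 of 18 with 2 higher (camera adjusted p = 0.00844, 0.039 and 0.00844, but adjusted p = 0.222, 0.191 and 0.277 with an estimated correlation, and 0.0502 for the immediate early list with total counts). With p-values adjusted over the list alone, 25 T cell and 6 glycolysis genes passed, with the counts outside MHC class I otherwise the same. The largest decreases were those of ENSG00000265150 (−2.65), ENSG00000258486 (−2.46), 7SK (−1.88), RMRP (−1.83) and SNORD3A (−1.76). With the lane pair as a term all turned upward, to 0.14, 0.36, 0.78, 1.61 and 1.04, none past the test.

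The CAF-rich step, mixture C against mixture F (2.4 against 0.8% TIL), changed fewer genes, nearly all of them upward. CD8A rose from 19.5 ± 2.03 to 56.3 ± 1.83 CPM, a log2 change of 1.53 ± 0.10 (edgeR adjusted p = 1e-18), and IL2RB from 41.8 ± 4.51 to 117 ± 8.93. PDCD1 rose by 3.13, from 0.163 to 1.57 CPM, but its level in F rests on 4 counts. The labelled shares predict a rise of 1.58 for a gene found in TIL alone. Across all genes, 333 rose and 10 fell, and 171 of those that rose changed at least 2-fold. Using only the C libraries of lanes 3 and 4, where all F libraries lay, 253 rose and 4 fell. T cell genes rose in 24 of 26 cases by a median of 1.36, cytotoxic effector in 17 of 20, activation in 7 of 17, myeloid in 3 of 5, NK cell in 6 of 8, MHC class II in 4 of 5 and MHC class I in 2 of 6. Their camera adjusted p-values were 6.77e-56, 2.82e-34, 2.79e-15, 0.000364, 1.59e-15, 6.52e-13 and 0.00768, and with an estimated correlation 2.1e-06, 1.11e-06, 8.19e-06, 0.00264, 8.19e-06, 1.96e-05 and 0.0172. Adjusted over the list alone, the counts were 26 T cell, 18 cytotoxic effector, 10 activation, 8 NK cell and 5 MHC class II genes, with the other counts the same. IL12RB2, a chain of the interleukin 12 receptor, rose by 1.84, TRAT1, a T cell receptor adaptor, by 1.75 and HLA-C by 0.29. Of the ribosomal protein genes, 1 rose and 19 did not pass the test (camera adjusted p = 0.179). Of the genes called lower at 1 CPM or more, MUC13, a membrane mucin gene, was furthest down, at −0.67, a call that neither DESeq2 nor the fit within lanes 3 and 4 gave.

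Across the 3 steps, the same lymphocyte genes moved. Higher in all 3 were 202 genes, every one of them higher in pure TIL than in both other populations, and 117 of them in the TIL signature. The calls higher in D against A and in C against F shared 243 genes, where independent lists of those sizes would share 45.1, and B against E shared 214 with C against F (40.7 for independent lists). Those of D against A and B against E shared 253 higher (142.6) and 1 lower (76.0), while 892 genes moved in opposite directions. The 200 TIL signature genes rose by a median log2 change of 1.01 in D against A, where the labels predict 0.98, by 1.21 in B against E (1.47 predicted) and by 1.38 in C against F (1.58 predicted). With the lane pair as a term those medians were 0.87, 1.35 and 1.43, with 52, 95 and 119 signature genes past the test against 159, 138 and 125 without it.

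**Figure D3:**
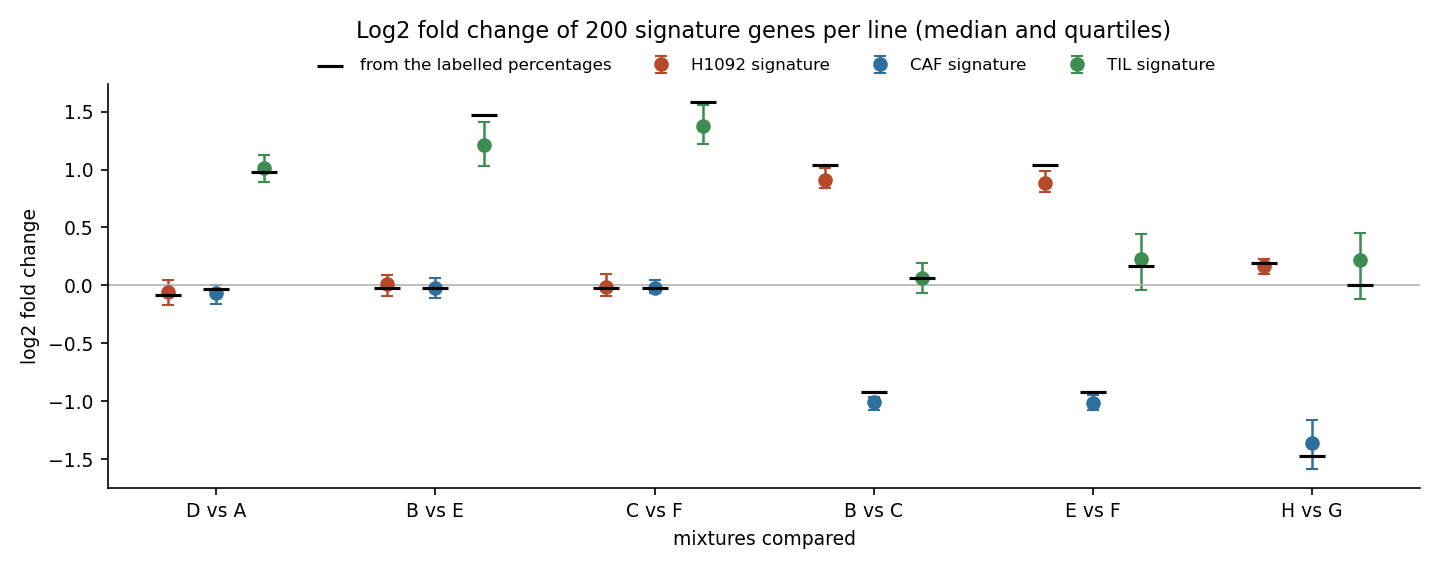
Median log2 fold change of the 200 signature genes of each population in the 6 comparisons of mixtures, with bars from the lower to the upper quartile. Black dashes mark the median log2 change of the same genes predicted from the labelled percentages and the pure levels. TIL genes rise by 1.01, 1.21 and 1.38 in the first 3 comparisons, and CAF genes have medians of −1.01, −1.02 and −1.36 in the last 3.

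Mixtures with similar TIL shares show the exchange of H1092 for CAF. In mixture B against mixture C (61.9 against 29.6% H1092), matrix and fibroblast genes fell, while the tight junction gene CLDN1 and the aldo-keto reductases AKR1C1 and AKR1B10 rose. COL6A3 fell from 5590 ± 262 to 2930 ± 132 CPM, a log2 change of −1.06 ± 0.04 (edgeR adjusted p = 8.93e-31), and PDGFRB from 516 ± 11.6 to 283 ± 16.5. CLDN1 rose from 75 ± 2.86 to 165 ± 6.42 CPM and AKR1C1 from 431 ± 16.5 to 807 ± 8.18. Of the tested genes, 2343 rose and 2283 fell, of which 215 and 285 changed at least 2-fold. With only the C library of lanes 1 and 2, where all B libraries lay, 1643 rose and 1762 fell, but this rests on 1 library and a spread taken from other groups; scaling by total counts gave 3522 and 1509 and moved the median of all genes from 0.021 to 0.149.

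Matrix genes fell in 19 of 20 cases, with a list median of −0.87, and fibroblast genes in 16 of 16 (camera adjusted p = 1.96e-10 and 1.63e-07, and adjusted p = 0.00835 with an estimated correlation for both). FBLN5 changed by −1.09, COL6A2 by −1.06 and CNN1 by −1.09. CHRD, which encodes the BMP antagonist chordin, changed by −2.27, to 0.755 CPM in mixture B. The labelled shares predict −0.93 for a gene found in CAF alone, and the CAF signature genes had a median of −1.01. The reason for the larger change of CHRD was not tested. NRF2 targets rose in 10 of 12 cases with 2 lower (camera adjusted p = 0.0186, but adjusted p = 0.0616 with an estimated correlation), with AKR1B10 up by 0.86 and HMOX1 at −0.72. Cholesterol synthesis genes rose in 4 of 8 cases (camera adjusted p = 0.0182, but adjusted p = 0.0552 with an estimated correlation). Glycolysis and hypoxia genes fell in 11 of 14 cases with 2 higher, immediate early and heat shock genes in 11 of 17 with 3 higher, and EMT regulators in 4 of 5 with 1 higher. Their camera adjusted p-values were 7.98e-05, 0.00506 and 0.0321, and none held as adjusted p = 0.0623, 0.0616 and 0.0616 with an estimated correlation. Epithelial genes rose in 6 of 10 cases with 1 lower (camera adjusted p = 0.0871), with EPCAM up by 0.88, or 0.54 and not past the test with the lane pair as a term, and DSP at −0.82. T cell genes rose in 3 of 26 cases (camera adjusted p = 0.777), and 1 of these was GATA3, a lineage factor that H1092 also carried, at 18.6 CPM in the pure line.

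At lower TIL shares and within lanes 3 and 4, matrix and fibroblast genes also fell in mixture E against mixture F (63.0 against 30.0% H1092). DCN fell from 2590 ± 46.0 to 1320 ± 38.1 CPM, a log2 change of −1.08 ± 0.03 (edgeR adjusted p = 2.83e-35), and COL6A3 changed by −1.07. The epithelial claudin CLDN4 rose by 1.04, from 37.8 ± 2.67 to 84.4 ± 4.2 CPM, and AKR1B10 by 0.92. NPW, which encodes the neuropeptide W precursor, rose by 2.26 and CD70, the ligand of CD27, by 1.37. Both rose by more than the 1.07 that the labelled shares predict for a gene found in H1092 alone, and the reason was not tested. edgeR called 2378 genes higher and 2263 lower, of which 222 and 261 changed at least 2-fold; with total counts the split was 3339 and 1599, and the median of all genes moved from 0.023 to 0.137. Calls shared with B against C numbered 1804 higher (647.7 for independent lists) and 1809 lower (600.6), with 30 in opposite directions. Matrix genes fell in 20 of 20 cases and fibroblast genes in 14 of 16 (camera adjusted p = 2.76e-10 and 3.64e-07, and adjusted p = 0.00894 with an estimated correlation for both). NRF2 targets rose in 9 of 12 with 2 lower, glycolysis and hypoxia genes fell in 10 of 14 with 2 higher, and ribosomal protein genes rose in 12 of 20 with 3 lower. Camera gave them adjusted p-values of 0.0223, 0.00495 and 0.00256, but adjusted p = 0.0998, 0.176 and 0.494 with an estimated correlation, and the glycolysis call also ended with scaling by total counts (0.0548). Epithelial genes rose in 8 of 10 cases with 1 lower (camera adjusted p = 0.0508, and 0.0389 with size factors). Cholesterol synthesis genes (4 of 8 higher), immediate early and heat shock genes (10 of 17 lower, 5 higher) and EMT regulators (3 of 5 lower, 1 higher), called in B against C, were not called here (camera adjusted p = 0.0755, 0.0791 and 0.0709), although total counts gave 0.0392 for the cholesterol and EMT lists, and for the reference list, at 0.348 with TMM. In B against C the ribosomal protein genes were not called (6 higher and 8 lower of 20, camera adjusted p = 0.89). Whether the lists differed between these comparisons was not tested. Adjusted over the list alone, 15 fibroblast and 4 EMT genes fell here and 16 fibroblast genes in B against C, with the other counts named for both comparisons the same.

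At the H1092-rich end, mixture H against mixture G (93.6 against 81.9% H1092, both in lanes 3 and 4) mostly lost stromal transcripts. COL6A3 fell from 1480 ± 53.6 (n = 3) to 480 ± 11.1 CPM (n = 2), a log2 change of −1.65 ± 0.05 (edgeR adjusted p = 1.37e-34). COL5A2 changed by −1.51, DCN by −1.37 and PDGFRB by −1.24. KCND3, a potassium channel gene, changed by −3.47 to 0.278 CPM, the largest decrease called at 1 CPM or more, and TEK, the angiopoietin receptor, by −2.14. The KCND3 level in H lay near the floor of 0.208 CPM, which 3 counts over the group give. The labelled shares predict −1.56 for a gene found in CAF alone. KCND3 and TEK exceeded that in size, COL6A3 slightly, and the reason was not tested. Lower were 920 genes and higher 422, of which 283 and 3 changed at least 2-fold, and total counts gave 822 lower and 666 higher. Of the genes higher in H, 406 were also higher in E against F (116.7 for independent lists), and of those lower 884 (242.0). Matrix genes fell in 19 of 20, fibroblast genes in 14 of 16 and EMT regulators in 3 of 5 with 1 higher (camera adjusted p = 7.09e-21, 3.82e-11 and 0.0024, and adjusted p = 0.000319, 0.000541 and 0.0126 with an estimated correlation). KRT19 rose by 0.29 and AKR1B10 by 0.26. Immediate early and heat shock genes fell in 7 of 17 with 2 higher, ribosomal protein genes rose in 6 of 20 and reference genes in 3 of 18 with 1 lower (camera adjusted p = 0.00568, 0.0024 and 0.0115, but adjusted p = 0.119, 0.422 and 0.277 with an estimated correlation). Cytotoxic effector genes rose in 2 of 20 cases (camera adjusted p = 0.00612, but adjusted p = 0.241 with an estimated correlation). For the T cell list, with a median of 0.28, 0 of 26 genes passed edgeR's test or DESeq2's and 2 had an unadjusted p under 0.05, while camera called the list at 0.0035 but gave adjusted p = 0.277 with an estimated correlation. Adjusted over the list alone, the counts were 15 fibroblast and 4 EMT genes lower, 1 cytotoxic effector gene higher, 4 reference genes higher, and 1 ribosomal protein gene lower beside 6 higher. Without library 1 of mixture H, 748 genes were called in all against 1342 with it.

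Whether the TIL step differed by background was tested as (B against E) against (C against F). Mixtures that are exact sums of their parts can also differ here, since a gene's log2 step depends on its level in H1092 and CAF. The labels themselves predict unlike steps for the TIL signature genes, with medians of 1.47 in B against E and 1.58 in C against F. Ribosomal protein genes were among those that differed. RPS15 differed by −0.45 ± 0.05 on the log2 scale (edgeR adjusted p = 1.59e-09), RPLP1 by −0.28 and RPL28 by −0.27. Of the ribosomal list 8 of 20 genes were lower, or 16 adjusted over the list alone (camera adjusted p = 2.42e-15, but adjusted p = 0.301 with an estimated correlation). Larger decreases came from ENSG00000265150 (−2.42), ENSG00000258486 (−2.22) and 7SK (−1.44), which with the lane pair as a term stood at −0.09, 0.14 and 0.76, none past the test. 7SK was not called by DESeq2, nor without library 2 of mixture B (−1.13), library 2 of C (−1.12) or library 3 of C (−1.15). Among other genes, NPW differed by −1.21, CD70 by −0.81, HLA-C by −0.31 and COL6A2 by −0.29, while RGPD3 differed by 0.83 and the tight junction gene OCLN by 0.72. NPW, RGPD3 and OCLN were not called by DESeq2, nor OCLN with the lane pair as a term. Immediate early and heat shock genes were lower in 3 of 17 cases, or 5 adjusted over the list alone, and glycolysis and hypoxia genes in 1 of 14, or 6 (camera adjusted p = 0.0119 and 0.025, but adjusted p = 0.301 and 0.624 with an estimated correlation). With total counts the T cell list, 1 of 26 genes lower, was called as well (adjusted p = 0.0411 against 0.0565). In all, the signed log2 step was higher in the H1092-rich background for 127 genes and lower for 272, and for 224 and 252 with total counts. A lower signed step can be a smaller rise or a larger fall. Mixture B lay in the other lane pair than E and F, and with the lane pair as a term the counts were 17 and 185. Within a lane pair no such comparison can be made. The count without 1 library fell to 185 without library 2 of mixture F, and stood at 224 and 245 without libraries 1 and 2 of mixture B, 237 without library 3 of C and 228 without library 3 of E.

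A last comparison asked, gene by gene, whether the mixtures on average equalled the weighted sum of their parts. In the mean over mixtures most genes lay close to it: over 5823 genes at 10 CPM or more, the median absolute departure was 0.033 on the log2 scale and the 95th percentile 0.111. Departures of opposite sign in single mixtures cancel in that mean, so it does not describe any single mixture. The shares used were estimated from the same libraries. Of 8398 genes tested, 8 departed by at least 1.5-fold, 6 above and 2 below the sum. The count moved with the settings, at 6 to 15 with a pure library left out, 35 with TMM-scaled CPM and 247 with no size threshold. Those above were small structural RNAs, 7SK by 2.15 ± 0.24 (SE, adjusted p = 1.64e-08), RMRP, the RNA of the ribonuclease MRP, by 2.40, the U3 small nucleolar RNAs SNORD3A and SNORD3C by 2.12 and 3.08, and ENSG00000265150 and ENSG00000258486 by 2.04 and 1.94. RMRP, SNORD3A, SNORD3C and KCNMB2-AS1 lay under the CPM minimum for naming and were chosen after their values were seen. KCNMB2-AS1, an antisense RNA whose reads cannot be told from those of an overlapping gene, lay below the sum, at −0.97, and under 1 CPM on average. Within lanes 1 and 2, 7SK departed by 0.21 and ENSG00000265150 by −0.05, against 2.91 and 2.88 for the mixtures of lanes 3 and 4. With mixtures of lanes 1 and 2 only, 0 genes were called, and 55 passed the size threshold at an unadjusted p under 0.05; no other tool was run for this test. 7SK averaged 8.58 ± 5.98 CPM in the 9 pure libraries, 6.26 ± 3.38 in the 7 mixture libraries of lanes 1 and 2, and 40.2 ± 8.04 in the 16 of lanes 3 and 4.

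**Figure D4:**
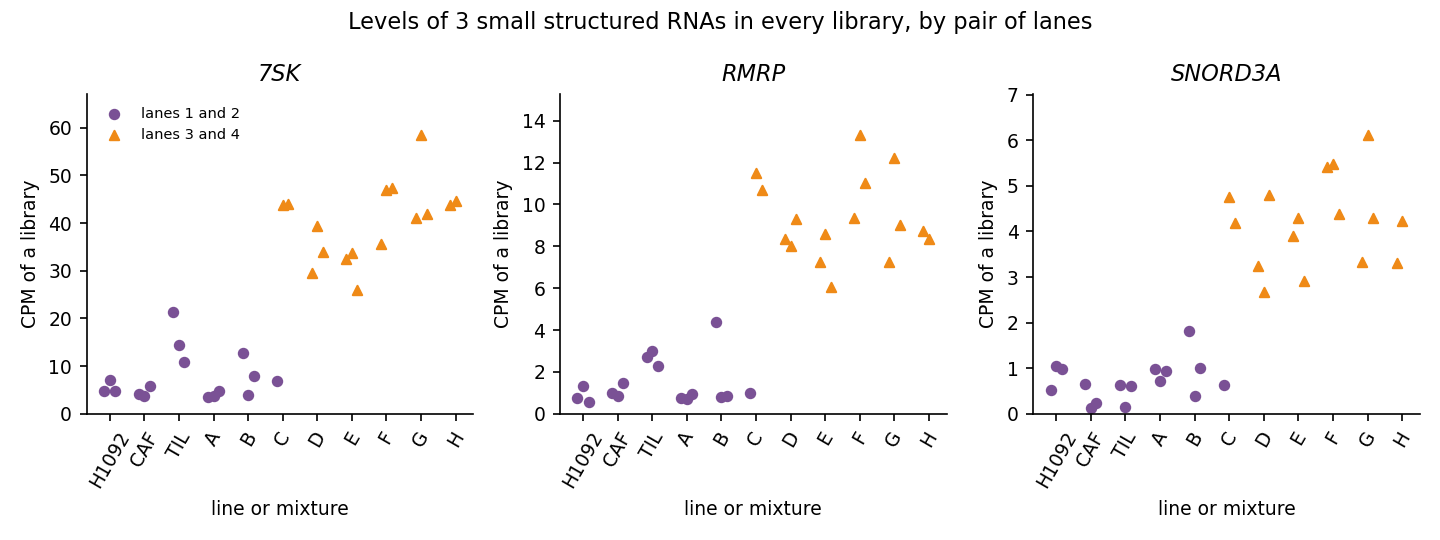
CPM of 7SK, RMRP and SNORD3A in each of the 32 libraries by group, with circles for lanes 1 and 2 and triangles for lanes 3 and 4. The 16 mixture libraries of lanes 3 and 4 average 40.2 CPM for 7SK, against 6.26 in the 7 mixture libraries of lanes 1 and 2.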

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

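Among the tests named here, those of shared direction in both contrasts, of constant TIL content, of rounding, of cross-talk, of the lane term for ribosomal protein genes, of the departures below the sum and all counts over splits were chosen only after the results were seen, and the rule for constant TIL content was revised once its first value was known.

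The step in TIL share differed between the H1092-rich and the CAF-rich background for 399 genes by an edgeR test of the difference itself. Exact sums of the parts would give some such differences too, as a gene's log2 step depends on its level in H1092 and CAF. How many genes that predicts was not computed, so this explanation stays open. Of 60 drawn splits of the 12 libraries within each step, the real one included, 4 gave as many genes, a share of 0.067. All of these kept mixtures B and E apart, so the share cannot tell whether chance gave the count. The highest other split gave 1224 genes, which points to a structure of the samples: the 6 splits that kept mixtures B and E apart, and with them their TIL shares and lane pairs, gave at least 354 genes, and those that mixed them at most 234. Splits of the first kind hold a real step on 1 side and are not groupings by chance alone. Mixture B lies in another lane pair than mixture E, and with the lane pair as a term 202 genes were called.

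Small changes ran through mixture D against A and B against E, most visibly the opposite shifts of ribosomal protein genes. Over 7343 genes with a predicted change under 0.1, the 2 contrasts correlated across genes with r = −0.369, as a difference between lane pairs would need, since they cross the lane pairs in opposite directions (genes are not independent replicates). A larger TIL share in both is argued against by the genes called in both, of which 22.2% moved the same way; the share of called genes outside the signature in the predicted direction in D against A, 68.4%, lay between the bounds set for it. GC content and length took an R2 of 0.117, which leaves their part open. A lane pair difference may therefore be a cause, although the lane term, 1 library of mixture C against 2, called 29 of 8602 genes and 0 of 20 ribosomal protein genes (13 at an unadjusted p under 0.05, median 0.10, against 0.26 and −0.19 in the contrasts), and other differences between the mixtures stay open and untested.

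Small structural RNAs exceeded the weighted sum of the pure populations. With mixtures of lanes 1 and 2 alone, the median departure of 7 called genes was 0.105 times its value over all mixtures, as a difference between lane pairs would need. Within mixture C, at a single labelled composition, 7SK stood at 6.97 CPM in the library of lanes 1 and 2 and at 43.7 and 44.1 CPM in those of lanes 3 and 4, but 1 library cannot tell a lane pair from a trait of that library. Removal of duplicates would raise abundant genes above the sum, but the departure had a rho of −0.004 with counts per base across genes. For the 2 genes below the sum the ratio was 0.906, and at under 1 CPM the causes cannot be told apart; no biological explanation was tested.

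The estimated TIL share of mixtures G and H exceeded its label. A few signature genes do not account for it, since the median gene stood at 0.628% of its pure TIL level. A constant TIL content as the whole cause is argued against by content ratios 5.5 pooled SDs between libraries above those of mixtures A to D; with the label at its upper rounding bound, the excess over a single ratio was 4.79 SDs between mixtures A to F on the log2 scale and 2.52 in points, which argues against rounding as the whole cause too. Cross-talk between libraries is argued against by a TIL signature of 0.012% in pure CAF, but those libraries lie in lanes 1 and 2 while G and H lie in lanes 3 and 4. An error in mixing, which may be larger at a share of 0.4%, stays open and was not tested as a cause.

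With 3 libraries against 3 there are 10 splits, too few for a share under 0.05. In each of the 8 such contrasts only the real split, 1 of 10, reached its count of genes. The real counts were 6911, 7657, 7338, 2118, 1739, 343, 4626 and 4641 for H1092 against CAF, H1092 against TIL, CAF against TIL, D against A, B against E, C against F, B against C and E against F. The highest other splits gave 0, 0, 0, 3, 0, 0, 6 and 0. For lists, 1 split reached the 9 called in H1092 against CAF (highest other 8), 2 reached the 13 in H1092 against TIL (13) and 2 the 14 in CAF against TIL (14).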

How the results depend on the processing

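The fits within a lane pair were chosen only after the data were seen. Of the comparisons' values, 451 kept their direction and side of the threshold (counts within 1.5 times), 33 moved, 16 reversed, 2 became stronger and 7 weaker; of the named genes' values 1973 kept them, 49 lost the call and 7 reversed, all with the lane pair as a term. These were the largest decreases in mixture B against E, 7SK at 0.78, ENSG00000265150 at 0.14, ENSG00000258486 at 0.36, RMRP at 1.61 and SNORD3A at 1.04, and in the difference between backgrounds ENSG00000258486 at 0.14 and 7SK at 0.76, none past the test. No paired analysis was possible because the labels give no replicate numbers. A minimum of 2-fold, which only removes genes, left 3525 genes in H1092 against CAF, 4938 in H1092 against TIL, 4505 in CAF against TIL, 169 in D against A, 190 in B against E, 171 in C against F, 500 in B against C, 483 in E against F, 286 in H against G and 8 for the difference between backgrounds. With the lane pair as a term, 184, 237 and 202 genes were called in D against A, B against E and for the difference between backgrounds. With fewer reads, the first lane file gave 1121 in B against E, 888 in H against G and 230 for the difference, and the second 1340 in D against A, 1090 in B against E and 181 for the difference.

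Leaving out each library gave 6716 to 6868 genes in H1092 against CAF, 7488 to 7600 in H1092 against TIL, 7164 to 7229 in CAF against TIL, 1610 to 1896 in D against A, 1195 to 1537 in B against E, 257 to 361 in C against F, 4169 to 4484 in B against C and 4261 to 4354 in E against F. In H against G it gave 748 (without library 1 of H, which leaves a lone library assumed to vary like the others) to 1193. For the difference between backgrounds it gave 185 (without library 2 of F) to 531, with 224 and 245 without libraries 1 and 2 of B, 237 without library 3 of C and 228 without library 3 of E. Departing genes numbered 6 to 15, with 15 without library 2 of H1092, and r stayed at 0.9997 to 0.9999 for H1092 and CAF and 0.9961 to 0.998 for TIL.

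Mean offsets in points were −0.72 to −0.33 for H1092 with a library left out (−0.72, past the threshold, without library 1 of H1092), 0.71 to 1.07 for CAF and −0.38 to −0.35 for TIL. The H1092 offset was 0.34 with undivided CPM, 4.81 with TMM-scaled CPM, −0.67 (past the threshold) from the second lane file and 0.30 in lanes 1 and 2. The CAF offset was −0.03 with undivided CPM, −4.52 with TMM-scaled CPM, 0.22 with all tested genes and 0.92 in lanes 3 and 4, the last 2 not past the threshold, in lanes 3 and 4 at the smallest p that 6 mixtures can give before adjustment. The TIL offset was 0.36 with all tested genes and −0.66 in lanes 1 and 2. The log2 content ratio of CAF to H1092 ran from 0.0496 to 0.0755 with a library left out, and it missed the threshold without library 2 of C (0.052), without library 1 of F (0.0517), with 50 genes (0.0381), with all tested genes (0.0346) and in lanes 3 and 4 (0.0746); it was −0.0048 in lanes 1 and 2, −0.0122 with undivided and −0.3375 with TMM-scaled CPM. That of TIL ran from −0.0403 to 0.0085, above 0 without library 1 of H1092 (0.0085), library 1 of G (0.0043) and library 2 of H (0.0083); it was 0.0356 with 500 genes, 0.7053 with all tested genes, 0.0025 from the second lane file, 0.1003 in lanes 3 and 4 and −0.4052 in lanes 1 and 2. Departing genes numbered 247 with no size threshold, 35 with TMM-scaled CPM, 24 with every gene, 0 in lanes 1 and 2 (55 past the size threshold at an unadjusted p under 0.05) and 25 in lanes 3 and 4. The cause was not tested, except for the 2-fold minimum, the removed size threshold and settings with fewer reads, libraries or mixtures. For shares with TMM-scaled CPM it lies in the factors that divide the pure profiles.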

Other observations

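H1092 carried stromal transcripts that are not confined to CAF in these data. POSTN stood at 2030 ± 33.6 CPM in H1092 and 2280 ± 17.9 in CAF, and the mesenchymal transcription factor PRRX1 at 281 ± 1.04 and 305 ± 2.3. COL1A1 reached 8790 ± 429 CPM in H1092, while COL6A3 stood at 7.56 ± 0.212 and CD248 at 0.0431 ± 0.0746. DSP ran the other way for an epithelial gene, at 26.9 ± 2.21 CPM in CAF and 0.0643 ± 0.0557 in H1092. Lymphoid genes were also counted in H1092, with TNFRSF9 at 71.2 ± 0.594 CPM, CD70 at 23.2 ± 2.06 CPM and the T cell adaptor SKAP1 at 15.8 CPM.

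TIL counted PDGFRB at 211 ± 9.81 CPM and COL5A2 at 40.3 ± 1.65 CPM, while COL1A1 stood at 2.84 ± 1.19 CPM and COL4A1 at 0 counts.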
